A study of Mus musculus with 3 samples.

How the data were processed

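Gene expression was measured in mouse neural retina on the Affymetrix U74Av2 oligonucleotide array named in the sample titles, a 1-colour array on which each transcript is represented by 1 or more sets of short probes. The series held 3 arrays, each hybridised with RNA from a pool of retinas of 3 to 4 Rp1-knockout mice aged 10 days (postnatal day 10), taken between 1 and 2 pm, per the labels. The descriptions place all 3 arrays in 1 group. They give no replicate numbers, so the arrays were numbered 1 to 3 in accession order, and the numbers are names only. The labels do not say whether the pools shared animals, so the spread between arrays measures the spread between these 3 RNA samples. The title of the array of pool 1 lacks the rp1 tag that the titles of the other two carry, while its description gives the same genotype, which is the one used here. No array of a control genotype was analysed here, so no comparison between genotypes was made.

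The table deposited by the authors gives 1 intensity per probe set and array, on a linear scale. The software, its version and the background method are not given in the sources used here. The arrays had already been scaled as a whole: the means after trimming 2% of the values at each end were 500.26, 500.25 and 500.26. The deposited intensity values were therefore used without further scaling. The depth of an array has no counterpart in read counts, and the number of arrays limits the precision.

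The table listed 12488 probe sets and 1 blank row, which was dropped. The 66 control probe sets were kept out of the gene results, which left 12422. The platform annotation supplied with the data gave 1 gene symbol to 10833 of these, several symbols to 396 and none to 1193. Of the 10833, 10817 symbols were updated through their gene identifiers in a mouse gene table (assembly GRCm38.p6), and the others kept the annotation's symbol. Probe sets with several symbols were not named. The table carries no coordinates, so no positions are reported. A gene with several probe sets was represented by the one with the highest mean signal. Of 23 named genes with more than 1 measured probe set, the pool with the highest signal differed between probe sets for 13: Bcl2, Casp2, Cryge, Flt1, Gnao1, Hspd1, Map3k1, Pcp2, Rps24, Rps28, Sncg, Suds3 and Tmem129. Suffixes f, r, i and s in a probe set's identifier mark sets whose probes were chosen under relaxed rules or can bind related transcripts.

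A background floor was set on each array at the 90th percentile of its 19 bacterial and yeast control probe sets, which have no target in mouse RNA. The floors were 100.5, 124.8 and 120.4 signal units for pools 1, 2 and 3. Signals under the floor were set to it and log2 was taken. Probe sets with a mean signal above the mean floor (8327) entered the measures of spread and are called measured. Mean signal served to choose and filter probe sets and genes. Signals of different probe sets were not read as relative amounts of transcript, because each binds its target with its own strength.

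The test for variable genes used limma 3.58.1 in R 4.3.3: an intercept-only model, a robust fit of an F distribution with an intensity trend to the residual variances, the tail p-value of each probe set's variance, and Benjamini-Hochberg adjustment with a threshold of 0.05. It asks whether a probe set varied more between pools than others of like signal. Tested on simulated data with the real mean signals of the 8327 probe sets and 200 of them changed in 1 pool, it called 3 of 50 changed by 2-fold, 43 of 50 changed by 4-fold, all 50 changed by 8-fold, all 50 changed by 16-fold and 3 of 8127 left alone. The simulated noise was normal with 1 typical SD per bin of signal, so probe sets of like signal did not differ in true variance. These rates may therefore not carry over to the real data. For the genes of each list, p-values were also adjusted over the list alone, with no correction for the number of lists.

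For 25 gene lists fixed before the data were examined, the median log2 difference between each pair of pools was compared with 10000 random lists of the same size, matched on mean signal in 10 bins. A list was called where its absolute median exceeded that of 99% of the random lists. This describes these arrays and is not a test of conditions. A list needed 3 measured genes, which 24 lists had, giving 72 comparisons, of which 0.72 would pass by chance if lists behaved as random genes. In simulated data for 6210 genes, 2 of 100 lists of 5 genes and 1 of 100 lists of 12 genes were called with no shift, 5 and 16 with a shift of 0.25 on the log2 scale, 22 and 52 with a shift of 0.5, and 92 and 100 with a shift of 1. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the rest, and matplotlib 3.10.9 for the figures.

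The genes named were chosen by a rule fixed together with the lists: Rp1, up to 4 genes of each list with the highest mean signal, for called lists also up to 4 with the largest SD, the 12 variable probe sets with a symbol and the smallest adjusted p, and the 5 steadiest probe sets with a symbol among the 25% with the highest mean signal. Variable probe sets named outside the rule are marked as such. Some other genes outside the rule are named without a mark, such as further lens and Y-linked genes, genes not measured and control transcripts. The alternatives were quantile normalization, equal medians, 3 other floors, other filters, no intensity trend, an ordinary fit, other thresholds and ways to combine probe sets, and leaving out each array.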

Results

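Neural retinas of mice without Rp1, a microtubule-associated protein of the photoreceptor axoneme that is mutated in a form of retinitis pigmentosa, were profiled at postnatal day 10, while outer segments are still forming. The mice had a mixed background of 2 inbred strains. The data consisted of 3 arrays, 1 per pool of 3 to 4 mice, all in 1 group, so the comparisons below are between pools of mutant retinas. Signals are in scaled intensity units, and means are given ± SD over n = 3 pools. No probe set was assigned to Rp1 in the annotation used, and the targeted gene is not reported here. The loss of Rp1 was therefore not checked from these arrays.

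The arrays were alike in overall signal, which their scaling to equal trimmed means largely sets. Median signals were 234 in pool 1, 234 in pool 2 and 233 in pool 3, and signals reached from 0.6 to 74893.5, controls included. In pool 1, 8657 of 12422 probe sets (69.7%) lay above the background floor, against 8133 (65.5%) in pool 2 and 8226 (66.2%) in pool 3. On all 3 arrays together 7198 probe sets (57.9%) were above the floor, and 2898 (23.3%) were above it on none. At most 9 probe sets had exactly the same signal on any 2 arrays, so each array was counted once. Across the 8327 measured probe sets Pearson's r of log2 signal was 0.933 between pools 1 and 2, 0.934 between pools 1 and 3, and 0.941 between pools 2 and 3, with Spearman's rho of 0.914, 0.913 and 0.920. These are correlations across genes, which are not independent replicates. The median SD of log2 signal between pools was 0.268, and 90% of probe sets had an SD under 0.569. Between 425 (5.1%) and 576 (6.92%) probe sets differed by more than 2-fold in a pair of pools. The ratio of 3' to 5' signal of control transcripts, a measure of RNA integrity, was 0.82, 0.90 and 0.75 for Gapdh and 1.10, 1.40 and 1.63 for Actb in pools 1, 2 and 3.

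Rod phototransduction genes were detected on every array and were highest in pool 2. Of the rod phototransduction list, 13 of 22 genes had a named probe set, and all 13 were above the floor in all pools. Sag (rod arrestin) had a mean signal of 24889 ± 3820, Pdc (phosducin, which binds transducin subunits) 20890 ± 1353 and Pde6g (the inhibitory subunit of rod phosphodiesterase) 15911 ± 2638. The list's median log2 difference was -0.42 for pool 1 minus pool 2, beyond 99.80% of random lists, with 12 of 13 genes lower in pool 1. It was 0.34 for pool 2 minus pool 3, beyond 99.40% of random lists, with 11 of 13 genes higher in pool 2. Pools 1 and 3 differed by -0.15, inside the range of random lists. Gnat1 (the rod transducin alpha subunit) had signals of 3228.9, 6226.7 and 3765.6 in pools 1, 2 and 3. Pde6a (a catalytic phosphodiesterase subunit) had 784, 1225.6 and 673.4, and Cnga1 (the rod cyclic nucleotide-gated channel) 938.4, 1556.4 and 1182.3. None of these 3 genes varied more than the intensity trend (limma, adjusted p of 0.83 for Gnat1 and 0.99 for Pde6a and Cnga1). Lens genes moved the other way between these pools, with a median of 1.84 for pool 1 minus pool 2 and -2.75 for pool 2 minus pool 3. The call for pool 2 minus pool 3 was lost among the 25% of probe sets with the highest mean signal (0.34) and with the mean of all probe sets of a gene (0.29), and neither call of the rod list held at the strictest threshold.

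Gnb1 (the transducin beta subunit) was highest in pool 3, unlike the rod list as a whole. Its signals were 5367.5, 8246 and 19075.3 in pools 1, 2 and 3, a range of 3.55-fold that passed the test of variability (limma, adjusted p = 0.042). Its other probe sets kept the same order, with 2112.2, 2850.8 and 4996.4 for one and 4934.2, 5467.4 and 13308.4 for the other, although neither passed (limma, adjusted p of 0.59 and 0.18). The call was lost in 6 of 12 alternatives, with adjusted p from 2.8e-06 to 0.98 over the 12 (limma): after quantile normalization (0.051), with the floor at the median control, among the 25% with the highest signal, without pool 3, with an ordinary fit and with no intensity trend. Gnb1 was the 1 gene of 13 in the rod list that passed, both over all probe sets and adjusted over the list alone.

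Genes of the outer segment and connecting cilium had a median SD of 0.18 on the log2 scale, against 0.214 for the 25% of probe sets with the highest mean signal, and Prph2 stood apart from the rest. All 9 measured genes of this list lay above the floor in all pools. Unc119 (a trafficking factor for lipidated photoreceptor proteins) had 11994 ± 418, Tulp1 (a photoreceptor trafficking protein) 11372 ± 1486, Prom1 (prominin, at the base of the discs) 10154 ± 1166 and Rom1 (a disc rim protein) 5106 ± 293. A second Rom1 probe set, of the f class, was less steady at 754.2, 2033.6 and 991.4. The list's median log2 difference was -0.06, -0.08 and 0.14 for pools 1 minus 2, 1 minus 3 and 2 minus 3, all inside the range of random lists. Prph2 (peripherin, the partner of Rom1 in disc rims) had a signal of 9356.3 in pool 1, against 1469.1 in pool 2 and 1332.3 in pool 3, a range of 7.02-fold (limma, adjusted p = 0.0011). It was the 1 gene of 9 that passed, also adjusted over the list alone, and it did not pass without pool 1.

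The transcription factors of photoreceptor fate had a median SD of 0.31 on the log2 scale between pools. Crx had 8625 ± 807, Neurod1 4770 ± 650, Prdm1 766 ± 206 and Nrl, which directs rod fate, 500.2 ± 66.7. Of the 8 factors with a named probe set, 6 were measured, and Mef2c and Rxrg were not. Cone genes were measured for 5 of 6 with a probe set: Gnb3 at 5947 ± 1032, the short-wave opsin Opn1sw at 1864 ± 182, Gnat2 (cone transducin) at 1222 ± 343 and Gngt2 at 676.4 ± 56.9. The channel gene Cnga3 was not. Neither list was called between any pair of pools.

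None of the lists of inner retinal cells and Müller glia was called between any pair of pools. Gad2 of the amacrine list and Vim of the Müller glia list were not measured, and 8 of 9 measured ganglion cell genes and 7 of 8 measured Müller glia genes were above the floor on all arrays. Bipolar cell genes included Gnao1 at 5912 ± 905, Prkca (protein kinase C alpha of rod bipolar cells) at 431 ± 109 and Trpm1 (the ON bipolar channel) at 349.4 ± 54.7, while Pcp2 had 1493.1, 848.9 and 2023.1 in pools 1, 2 and 3 by 1 probe set and 224.6, 312.5 and 218.6 by another, in which pool 2 was highest. Among amacrine genes, Calb2 (calretinin) had 3686 ± 485, the glycine transporter Slc6a9 2312 ± 427, Gad1 (a GABA-synthesising enzyme) 2117 ± 281 and Slc32a1 (the vesicular inhibitory transporter) 1777 ± 432. This list had a median of 0.40 for pool 1 minus pool 2, beyond 98.27% of random lists and short of the threshold. Horizontal cell genes were measured at 618 ± 197 for Prox1, 415.0 ± 60.9 for Calb1 (calbindin) and 316.2 ± 27.0 for Lhx1. Ganglion cell genes included Stmn2 at 2615 ± 208, Gap43 (a growth cone protein) at 1591 ± 370, Thy1 at 1281.7 ± 89.5 and Sncg at 924.1 ± 58.2. Müller glia genes included Car2 (carbonic anhydrase) at 7536 ± 379, Apoe at 5208 ± 1283, Dkk3 at 2927 ± 610 and Rlbp1 (the retinal-binding protein of the visual cycle) at 2673 ± 595.

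None of the lists of gliosis, microglia, apoptosis and JNK signalling was called between any pair of pools. Of 10 gliosis and stress genes with a probe set, 5 were measured, among them Stat3 at 1152.6 ± 311.7, Gfap (the glial filament raised in damaged retina) at 259.5 ± 25.3 and Cebpd at 202 ± 36. Serpina3n, an acute-phase protease inhibitor, had 162, 658.6 and 709.6 in pools 1, 2 and 3 and did not pass the test over all probe sets (limma, adjusted p = 0.16), though it was the 1 gene of 5 that passed when adjusted over the list alone. Edn2 and Fgf2 were not measured. Microglial genes included C1qc at 700 ± 104, Cd14 at 546.8 ± 67.0, Ctss at 395.1 ± 56.7 and Cx3cr1 at 392.3 ± 69.9. Apoptosis genes included Bcl2l1 (an anti-apoptotic protein) at 1444.5 ± 53.8, Casp2 at 1133.7 ± 81.2, Aifm1 at 1119 ± 208 and Bcl2 at 442.4 ± 32.7. The median SD of the 9 measured genes of this list was 0.13 on the log2 scale. In the JNK pathway the 12 measured genes had a median SD of 0.14: Map3k1 (an upstream kinase) had 2090.3, 2102.4 and 2129.4 in pools 1, 2 and 3, Mapk8 (JNK1) 1725 ± 143, the scaffold Mapk8ip1 1463.2 ± 67.5 and Jund 10620 ± 2361.

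No list of proliferation, time of day, stress response or general metabolism was called between any pair of pools. Of 20 cell cycle genes with a probe set 14 were measured, with Pcna at 909 ± 149, Ccnd1 (cyclin D1) at 890 ± 291, Mcm7 at 772 ± 114 and Ccna2 at 669.2 ± 38.1, whereas the proliferation markers Mki67 and Top2a were not. Clock genes included Arntl at 1634 ± 220, Tef at 1254 ± 239, Cry1 at 1097 ± 155 and Nr1d2 at 874.7 ± 91.4. Immediate early genes included Btg2 at 3632 ± 457, Egr1 at 455.4 ± 88.4, Ier2 at 437.7 ± 60.4 and Fosb at 437.6 ± 28.7, and Fos was not measured. Among heat shock genes Hspa8 had 5509 ± 521 and Hspa5 3221 ± 594. Hsp90aa1 was at 16122.3, 20971 and 9307.4 and Hspd1 at 1177, 1346.9 and 2802.2 in pools 1, 2 and 3, and neither passed the test over all probe sets (limma, adjusted p of 0.47 and 0.6), while both passed among the 9 genes when adjusted over the list alone. A second Hspd1 probe set, of the r class, ran the other way at 334.7, 254.1 and 235.4. The 53 measured genes of oxidative phosphorylation had a median SD of 0.21, with Cox6a1 at 10129 ± 1673, Atp5mpl at 8733 ± 1661, Atp5a1 at 8557 ± 1050 and Cox6c at 8283 ± 209. This list had a median of -0.14 for pool 1 minus pool 3, beyond 97.11% of random lists and short of the threshold. The 28 ribosomal protein genes had a median SD of 0.15, with Rpl41 at 37002 ± 4108, Rps24 at 26088 ± 2457, Rps28 at 21999 ± 2278 and Rplp0 at 14464 ± 2322. The steadiest named probe sets among the 25% with the highest mean signal were those of Plcd1 (690.8 ± 2.0), Spef1 (720.4 ± 2.6), Sprr1b (5132.3 ± 30.4), Uqcc2 (905.6 ± 5.5) and Suds3 (996.1 ± 6.2). The Sprr1b set is of the r class, and another Sprr1b set, of the f class, was under the floor in all pools (67.1, 36 and 33.9). A second Spef1 probe set was above the floor in pool 3 alone (163.6). A second Suds3 probe set, of the s class, had 999.5, 758.3 and 697.5 in pools 1, 2 and 3.

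Lens genes had the largest median difference in each pair of pools among the 24 lists with at least 3 measured genes. All 11 measured lens genes were highest in pool 3, lower in pool 1 and lowest in pool 2. The median log2 difference was 1.84 for pool 1 minus pool 2, -1.08 for pool 1 minus pool 3 and -2.75 for pool 2 minus pool 3, each beyond 100% of the random lists, whose central 99% lay between -0.37 and 0.28 for the last pair. Cryaa (alpha-A crystallin) had signals of 18251.8, 3496.7 and 40575.6 in pools 1, 2 and 3, a range of 11.6-fold (limma, adjusted p = 0.0003). Crygs (gamma-S crystallin) had 5709.8, 1552.9 and 20456.4, a range of 13.2-fold (limma, adjusted p = 0.0003). Crygc ranged 9.96-fold, Crybb2 8.54-fold, Cryba1 7.75-fold, Crygd 6.74-fold and Crygb 6.05-fold, and each passed the test (limma, adjusted p of 0.00065, 0.001, 0.00069, 0.00084 and 0.0041). The probe sets of Cryge ranged 6.92-fold and 6.51-fold (limma, adjusted p = 0.00084 for both). The gamma crystallin probe sets of the f class can bind one another's transcripts, so these genes are not separate counts. Other probe sets disagreed for Crybb2 (798.8, 846.6 and 991.3) and Cryge (202.3, 241.3 and 207.7), both of the r class, and further ones of Cryge and Crygd were under the floor on all arrays. A second Crygb probe set (306.3, 166.7 and 465.3) had the same order and did not pass (limma, adjusted p = 0.89). A second Cryab probe set was above the floor in pool 1 alone (202.9, 15.1 and 95.6). Cryab (847.1, 404.6 and 1536.3), the membrane channel gene Mip (445.1, 127.8 and 459.7) and the filament gene Bfsp1 (430, 171 and 735.8) had the same order and did not pass over all probe sets. Of the 11 genes 8 passed over all probe sets and 11 adjusted over the list alone. The gap junction gene Gja3 was not measured. Of the single lens probe sets, limma called only Crygs without pool 2 and only Cryaa without pool 3, and with an ordinary fit Cryba1, Crygd, Crygb and both probe sets of Cryge lost their call.

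**Figure D1:**
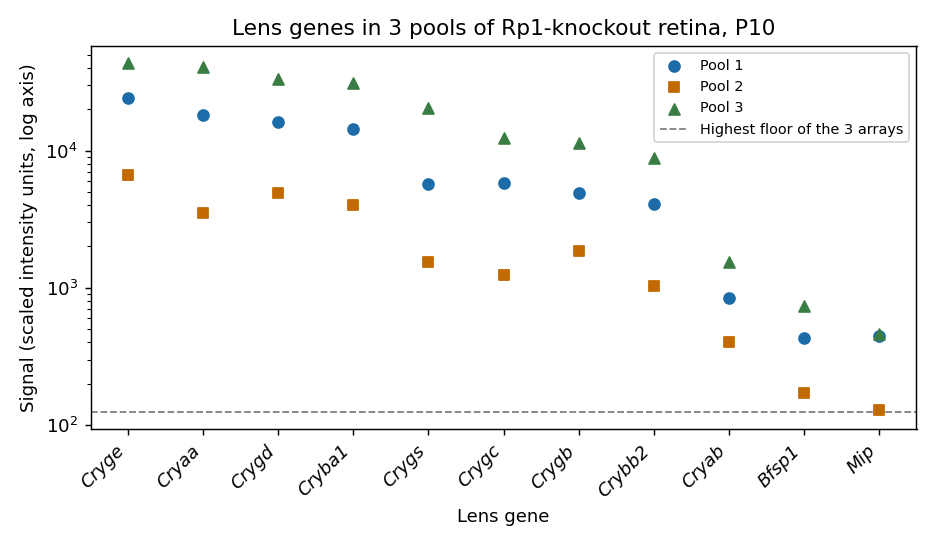
Signal of the 11 measured lens genes (log axis, scaled intensity units) on each array, 1 point per pool, with the highest of the background floors (124.8) as a dashed line. Every gene was highest in pool 3 and lowest in pool 2, with Cryaa at 40575.6 and 3496.7.

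None of the lists for pigment epithelium, blood, skeletal muscle and endothelium was called between any pair of pools. Of 10 pigment epithelium genes with a probe set 5 were measured, with Dct at 533 ± 104, Rrh at 424.9 ± 15.7 and Ttr at 202.6 ± 32.1. Pmel, a melanosome protein, was at 319.7, 327.7 and 908 in pools 1, 2 and 3. It did not pass the test over all probe sets (limma, adjusted p = 0.59), though it passed adjusted over the list alone. The same held for Hba-a1 in the blood list (limma, adjusted p = 0.63 over all probe sets). Tyr and Tyrp1 were not measured. Haemoglobin genes had 16422.3, 9461.1 and 8110.5 (Hba-a1) and 3819.7, 2995.5 and 2195.6 (Hbb-b2), and the blood list reached 0.56 for pool 1 minus pool 3, beyond 97.26% of random lists and short of the threshold. Of 12 skeletal muscle genes 6 were measured, 3 of them above the floor on all arrays, with Ckm at 207.3 ± 20.9. Endothelial genes included Kdr at 670.3 ± 70.4, Cldn5 at 490 ± 115, Pecam1 at 270.9 ± 57.9 and Flt1 at 166.5 ± 47.3. A second Flt1 probe set was above the floor in pool 1 alone, at 354.1.

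**Figure D2:**
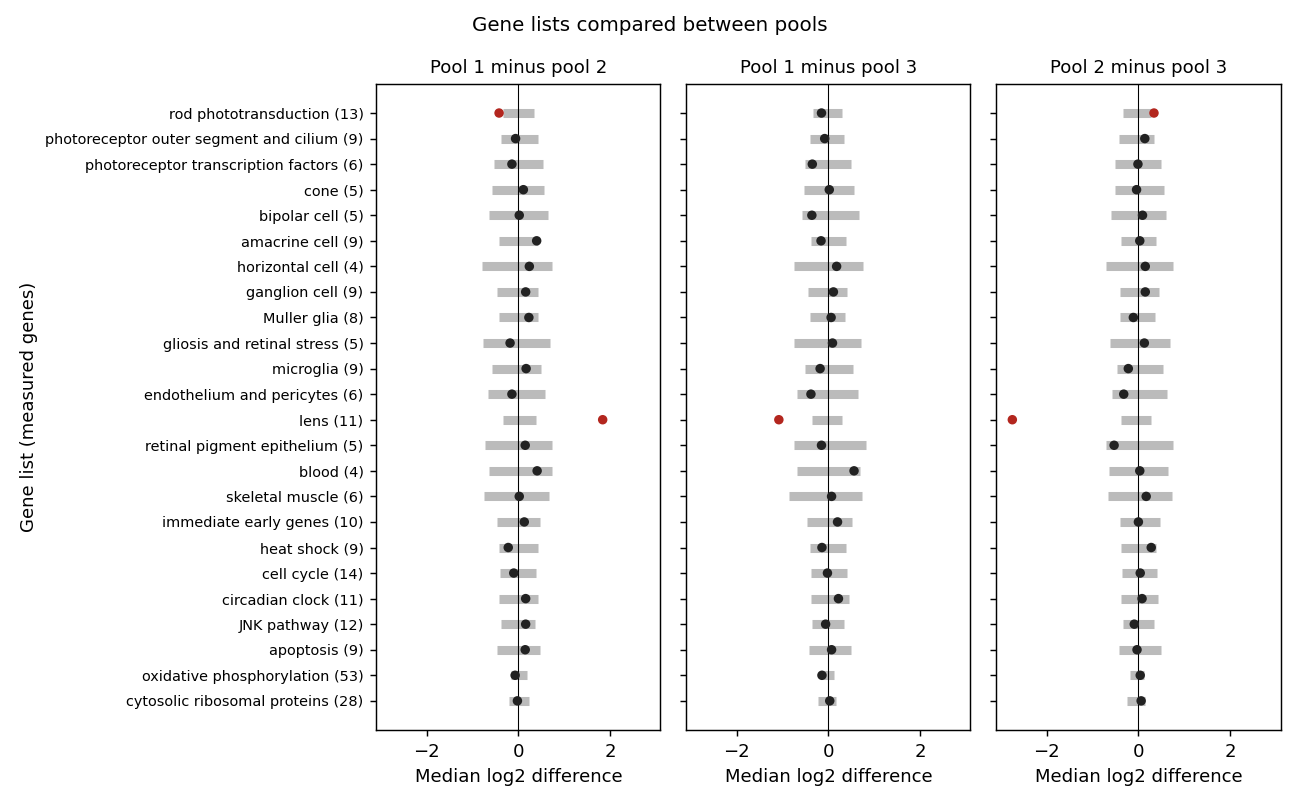
Median log2 difference of each gene list (points, red where called) for the 3 pairs of pools, with grey bars for the central 99% of matched random lists and the number of measured genes in parentheses. Only the lens list (-2.75 to 1.84) and the rod phototransduction list (-0.42 and 0.34) lay outside.

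Gene by gene, 18 of 8327 measured probe sets varied more between pools than the intensity trend (limma, adjusted p below the threshold of 0.05). An unadjusted p under 0.05 was found for 445, near the number that the fitted distribution alone would give. Of the 18, 9 belonged to 8 lens genes. Of the genes in the fixed lists, 11 in 4 lists passed over all probe sets and 19 in 8 lists passed adjusted over the list alone. Xist, the RNA that coats the inactive X chromosome of females, was at 69.5 in pool 1, under the floor, and at 1384.4 and 1543.7 in pools 2 and 3 (limma, adjusted p = 0.00063). Against the floor of pool 1, it was at least 13.8-fold higher in pool 2 and at least 15.4-fold higher in pool 3. Of the Y-linked genes, Eif2s3y was above the floor on all arrays at 546.4, 428.8 and 247, from a probe set of the f class, and did not pass the test (limma, adjusted p = 0.99), while Kdm5d and Uty were not measured. Ankrd33b, an ankyrin repeat gene, was at 1682.3 in pool 1 and under the floor in pools 2 and 3, at least 13.5-fold higher (limma, adjusted p = 0.0041). Beside Prph2 and Gnb1, the remaining calls were Tmem129, Snrp1c-ps2, Thrap3, Rnf26 and 1 probe set without a symbol (127.2, 860.6 and 677.4), which were singled out after their values were seen. Tmem129 (103.8, 735.1 and 862.3) and Thrap3 (916.8, 178.3 and 941.6) each had another probe set that did not pass the test, at 615, 694.4 and 550 and at 3097.7, 2683.3 and 3153. The called probe set of Tmem129 is of the r class. Snrp1c-ps2, a pseudogene, was at 288.5, 1549.9 and 1483.2, from a probe set of the f class, and Rnf26 at 634.5, 143.2 and 959.8. Tmem129, Thrap3, Rnf26 and the probe set without a symbol each lost their call under at least 1 other floor, and Ankrd33b among the 25% with the highest mean signal. With an ordinary fit limma called 6 of the 18, those of Crygs, Cryaa, Crygc, Crybb2, Xist and Prph2. The count was 4 without pool 3, 10 without pool 2 and 40 without pool 1. Xist, Prph2 and Ankrd33b were called without pool 2 and without pool 3. Without pool 1, Xist and Prph2 were not called, and Ankrd33b, with a mean of 116.5, fell under the filter and was not tested. With no intensity trend in the variance, limma called 0 probe sets, with 377 at an unadjusted p under 0.05.

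**Figure D3:**
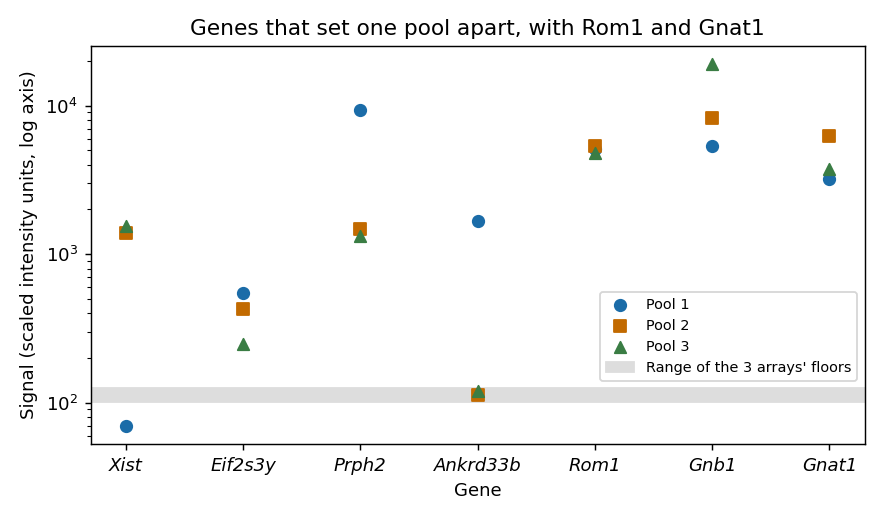
Signal of single genes (log axis, scaled intensity units), 1 point per pool, with the range of the 3 background floors (100.5 to 124.8) in grey. Xist was under the floor in pool 1 and Ankrd33b in pools 2 and 3, Prph2 was highest in pool 1 (9356.3), and Rom1 was nearly level (5106 ± 293).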

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

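The test without the lens genes and the 3' to 5' ratio after quantile normalization were chosen after seeing the data, the others before. The number of probe sets above the floor on all arrays (7198) depended on the floor. It was 5836 at the highest background control, 8880 at the median control and 5412 at the array median. With a pool left out it was 7460 to 7628, and all these counts were within 1.5 times 7198. The median SD between pools (0.268) was 0.242 with the floor at the highest background control, 0.318 at the median control, 0.235 at the array median, 0.197 with no filter, 0.214 in the 25% with the highest signal, 0.299 after an arcsinh transform and 0.212 to 0.232 with a pool left out. The lowest correlation (0.933) fell to 0.913 with the floor at the median control and was 0.932 to 0.938 with a pool left out. The 18 variable probe sets depended on the filter, the model of the variance and the pools used: limma called 52 with no filter, 6 with an ordinary fit, 0 with no intensity trend (377 at an unadjusted p under 0.05), and 4 to 40 with a pool left out. Without the lens genes 5 of the other 9 were called (Xist, Prph2, Ankrd33b, Tmem129 and Snrp1c-ps2), since fewer small p-values make the adjustment stricter. Quantile normalization kept 17 of the 18 and lost Gnb1, and equal medians kept all 18. The 2 called lists became 4 with the floor at the highest control and also 4 at the array median (Müller glia and blood added), 5 at 95% of random lists, 1 at the strictest threshold (lens) and 1 to 3 with a pool left out (lens alone without pool 2, pigment epithelium added without pool 1), where fewer pairs of pools remain and the filter on mean signal is set anew. Of 40 medians of the called lists under alternatives with all 3 arrays and the main threshold, 38 kept their call and 2 lost it. The 2 were of the rod list for pool 2 minus pool 3 (0.34 in the 25% with the highest signal and 0.29 with the mean of all probe sets). None of the 40 changed direction. The strictest threshold is not among the 40, and there the rod list also lost its call for pool 1 minus pool 2. All 236 means of named genes after quantile normalization or with equal medians moved by less than their SD. Leaving out 1 of 3 pools cannot move a mean by more than its SD, but 13 of 354 such means moved by over 1.5 times: those of Ankrd33b (638.4 to 116.5) and Prph2 (4052.6 to 1400.7) without pool 1, and those of Gnb1 (10896.3 to 6806.8), Pmel (518.5 to 323.7) and 9 lens probe sets (Crygs most, 9239.7 to 3631.4) without pool 3. The mean log2 ratios of 3' to 5' signal after quantile normalization (-0.27 for Gapdh and 0.39 for Actb) lay within 1 SD of those as deposited. Beyond the cause given, the cause was not tested. Signals under the floor, and 3 arrays of 1 group, limit what these data can show. No paired analysis was possible because there is 1 group.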

Other observations

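The lens median after quantile normalization, the rod median and the correlations come from planned analyses, but their use as tests and the other tests below were chosen after the results had been seen. The design, with 1 group, names no biological difference between the pools.

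Beta-actin gave partly opposite answers by probe set. The control probe sets for Actb were higher in pool 1 than in pool 2 by 2.52-fold at the 5' end, 2.40-fold in the middle and 1.98-fold at the 3' end, and higher than in pool 3 by 2.18-fold, 2.19-fold and 1.47-fold. The Actb probe sets outside the controls were highest in pool 3: one, of the f class, was at 2167.3, 3499.7 and 4451.5 in pools 1, 2 and 3, and another, at 6390.9, 5835.3 and 9583.1, was higher in pool 1 than in pool 2, as the controls were. Gnao1, a G protein gene of the bipolar list, also differed by probe set. One of its dimmer ones had 356.6, 79.5 (under the floor) and 346.9 in pools 1, 2 and 3. Its brightest had 4890.6, 6617 and 6227.2. The other measured ones were highest in pool 2, as the brightest was, at 330.6, 375.5 and 260.1 and at 361.4, 707.1 and 552.9.

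Lens genes were highest in pool 3 and lowest in pool 2, with Cryge at 43192.7 and 6639.9 and Cryaa at 40575.6 and 3496.7. Scaling is argued against, since the median of pool 2 minus pool 3 was -2.65 after quantile normalization against -2.75 as deposited. Outside the list, 22 probe sets had the order pool 3, pool 1, pool 2 with both steps at least 0.5 on the log2 scale. The other 5 orders had 25 to 61, so there was no excess of large steps in the lens order. This does not exclude a transfer of other lens transcripts, since the orders need not be equally common and smaller rises are not counted. Lens tissue carried over in unequal amounts when the retina was removed is a candidate explanation that stays open: 11 of 11 measured lens genes shared that order, but this order prompted the explanation, gamma crystallin probe sets can share targets, and Mip was nearly level between pools 3 and 1 (459.7 and 445.1). Crystallin expression by the retina itself, known for several crystallins, stays open as well, because only 2 measured lens genes are no crystallins (median 1.98 for pool 3 minus pool 2) and Mip is close to the floor in pool 2.

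Rod genes were highest in pool 2, the pool with least lens signal. If lens RNA diluted retinal RNA and the scaling did not undo it, other retinal cell types would be lower in pool 1 as well. The arrays were scaled to equal trimmed means, which can hide an even dilution, so neither test below can decide on it. The 40 measured genes of 6 other retinal lists had a median of 0.14 for pool 1 minus pool 2, against -0.42 for rods. The 95% interval from a bootstrap over genes was -0.22 to 0.44. It just reaches the bound of 0.5 times the rod value, so this test leaves dilution open. Intervals of this kind, here and below, measure the spread among genes and not between pools. Dilution growing with the lens signal, if not undone by the scaling, would put rods lower in pool 3 than in pool 1. The rod median of pool 1 minus pool 3 was -0.15 (-0.33 to 0.19), which does not decide.

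A few probe sets set pool 1 apart: Xist was under the floor, Prph2 and Ankrd33b were high, and Snrp1c-ps2 (288.5 against 1549.9 and 1483.2), one probe set of Tmem129 (103.8 against 735.1 and 862.3) and 1 probe set without a symbol (127.2 against 860.6 and 677.4) were low. The Snrp1c-ps2 set is of the f class and that of Tmem129 of the r class. A loss that silenced many bright probe sets on the array of pool 1 is argued against. Of 1691 probe sets above 1000 in both other pools, 1 was under the floor in pool 1, and it was Xist. That count cannot show an even loss across the array, because the scaling to equal trimmed means would undo it. Nor can it show a partial loss or a defect at a few probe sets. These stay open. A wider rise of outer segment transcripts is argued against for Prph2, since the other 8 genes of that list had a median of -0.03 (bootstrap over genes, -0.29 to 0.32) for pool 1 minus the mean of the others, against 2.74 for Prph2. For Xist, a pool of males is a candidate explanation. Eif2s3y was higher in pool 1 than the mean of the others by 0.75 on the log2 scale, and by 0.35 against pool 2 alone. It was -0.80 for pool 3 minus pool 2. These steps do not speak against the explanation, since pools 2 and 3 may have held unequal shares of males, which was not tested. Eif2s3y was the only measured Y-linked gene, so sex stays open. Uty was just above the floor in pool 1 alone, at 124.7, and Kdm5d was under it in all pools. Another genotype or strain mix in pool 1, whose title lacks the rp1 tag of the other two, stays open too: its correlation with the other pools (lowest 0.933, against 0.941 between pools 2 and 3) could not show a change at few loci, and no probe set was assigned to Rp1.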
